A study of Homo sapiens with 2 samples.

How the data were processed

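RNA of HES2 cells, an established human embryonic stem cell line, was sequenced in 2 libraries, 1 from cells expressing PB and 1 from cells expressing PB-Tcf1. The labels do not spell out PB, and the PB library served as the reference in every comparison. Per the labels, both cultures were kept for 2 passages in a basal medium containing KSR at 10%. FGF2 and Activin A were each added at 10 ng/ml, and IWR1, a tankyrase inhibitor that lowers Wnt/β-catenin signalling, was used at 4 µM. Total RNA was taken with Trizol and sequenced on a BGISEQ-500, per the labels' protocols, which also name Illumina library protocols. Tcf1 was read as T cell factor 1, the product of the TCF7 gene; the labels give neither a gene identifier nor the species of the construct.

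The submitters' processing notes name Bowtie 0.12.2 and the human build hg19. The counting tool, the gene annotation and the use of strand are not given in the sources used here. The deposited table has 18254 rows, each an Entrez gene or a locus named by a running number, and pairs 17612 of them with gene symbols, which were used as given. One expression value per gene and library was given. Its unit, FPKM (fragments normalized to gene length and library size), was inferred from the deposited values, since the header names no unit: multiplied by gene length in kilobases, the values summed to 1048790 in PB and 1053262 in PB-Tcf1, near the 1000000 that FPKM would give. The lowest value listed was 0.01, which stood in place of 0 for 1219 genes in PB and 1163 in PB-Tcf1. The authors' log2 fold change is the log2 ratio of the deposited expression values for all 18254 genes, floor included. The authors' p-values and their false discovery rates (FDR) were only counted, compared and used for the depth estimate. Their calls follow an absolute log2 fold change of at least 1 and an FDR of at most 0.001 in every row. Gene length, per the file headers, was used for read shares and estimates.

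The analysis had been laid out for read counts before the data were examined, with a second form for normalized values, and since the table holds FPKM the second form was used. The difference of a gene was log2(FPKM + 1) in PB-Tcf1 minus that in PB, with a pseudocount of 1 FPKM, so it understates the change of weakly expressed genes. Genes at 1 FPKM or more in one or both libraries passed the filter, 13502 in all, and a difference of at least 1 was counted as 2-fold. With 1 library per group there was no spread between replicates, no test between conditions and no p-value across genes. A ratio of FPKM values is given only where both libraries reach 1 FPKM, except for percentages of the PB level left in PB-Tcf1.

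Gene groups were described with 31 lists fixed before the data were examined. For each list the median difference of the members that passed the filter was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile among them describes these 2 libraries and is not a test of the conditions. Lists share some members. The list of mitochondrially encoded genes had 0 members under the symbols searched for and gave no value. The other 30 lists had between 4 and 30 passing members. The rule for named genes, also fixed beforehand, took 10 genes whatever their values (TCF7, LEF1, TCF7L1, TCF7L2, POU5F1, SOX2, NANOG, T, AXIN2 and SP5), the 12 symbols with the largest difference in each direction, and up to 2 members of each list in each direction. SOX17, FOXA2, GATA4, RNF43, SFRP2, VIM, HOXB6, HOXB7, DPPA2, FGF2, USP44 and RNR2 were named in addition after their values were seen. So were PECAM1, CD34, CDH5, TEK, TFAP2A, PAX3, TP63, KRT5 and KRT14. Some genes that the rule takes are not reported here.

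Read numbers are not in the table, and depth was estimated from it. Genes listed at the floor in one library carry stepped p-values that follow a Poisson comparison of read numbers in 2 libraries, and the step for 1 read put 50.80% of the reads of both libraries in PB and 49.20% in PB-Tcf1, a depth ratio of 1.032. The FPKM of 48 genes with 1 read in each library placed the depth at about 26600000 reads in PB and 25500000 in PB-Tcf1. Read numbers rebuilt this way gave back the deposited p-values with a median ratio of 0.987 on the log10 scale over 6836 genes. In a gene of 2000 bases, 1 read was worth 0.020 FPKM in PB and 0.021 FPKM in PB-Tcf1. The 95% intervals of ratios are Clopper-Pearson intervals on these estimated reads. They cover counting error only, and may be too narrow even for that, because reads without molecular identifiers are not independent molecules. They say nothing of variation between cultures.

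The counting rule and the list percentile were tested on simulated data for the comparison of PB-Tcf1 with PB, over 12288 genes. Both libraries were drawn around the geometric mean of each gene's values with an assumed noise of 0.15 (SD, log2), and the changed genes had a mean of 5 FPKM or more. The rule found 94 of 100 genes changed by 2 to the power 1.5 and 100 of 100 changed by 2 to the power 3, and it called 0 of 12088 unchanged genes. That 0 follows from the assumed noise, which was far below 2-fold. The noise held no counting error of weakly expressed genes and no variation between cultures. It therefore gives no rate of false calls for the real libraries. Of 20 lists of raised genes, 20 lay above the 97.5 percentile. Of 200 lists of unchanged genes, 15 (7.5%) lay outside the 2.5 to 97.5 percentiles. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

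Alternatives covered the scaling of the libraries, the filter, the pseudocount, the use of estimated reads with counting intervals, the authors' calls and random lists without matching. Total-count scaling, the values as deposited and 2-fold without an interval are the form used here and had no separate value. The reference annotation at hand is on another build, GRCh38, so no coordinates are given; its transcripts served only for GC content, matched by Entrez identifier.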

Results

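The data comprised 2 RNA-seq libraries of HES2 human embryonic stem cells, 1 expressing PB and 1 expressing PB-Tcf1. Both cultures received FGF2 and Activin A, which hold human embryonic stem cells in the primed pluripotent state, and the Wnt pathway inhibitor IWR1. The series title states the purpose of finding genes regulated by Tcf1. Depth, estimated from the table, was about 26600000 reads for PB and 25500000 for PB-Tcf1. At 1 FPKM or more, 12347 genes were detected in PB and 12330 in PB-Tcf1. There were no replicates, so each difference below is one between 2 libraries, with no check of its variation between cultures.

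TCF7 (Entrez 6932), the gene the construct is named for, was listed at 8.31 FPKM in PB and 24.97 FPKM in PB-Tcf1, a ratio of 3.0 with a counting interval of 2.72 to 3.26. The direction was that of the labels. Whether these reads came from the construct or from the cell's own gene was not given. The other genes of the TCF/LEF family moved the opposite way or were hardly expressed. TCF7L1 (83439), a transcriptional repressor at Wnt target genes, was at 84.5 FPKM in PB and 40.8 in PB-Tcf1. TCF7L2 (6934) went from 25.5 to 9.74 FPKM between the same libraries. LEF1 (51176) was at 0.21 and 0.74 FPKM, under the filter. Across the list of TCF/LEF genes and Wnt signal transducers, 6 of 26 measured members were 2-fold or more higher, 3 were 2-fold or more lower, and the median difference of 0.30 stood at percentile 88.2 of matched random lists, and was 0.19 under median-of-ratios scaling. Its largest differences were in the co-repressor genes TLE2, higher with 4.67 FPKM in PB and 23.0 in PB-Tcf1, and CTBP2, lower with 81.7 and 28.2 FPKM.

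Of 13502 genes that passed the filter, 2209 (16.4%) were 2-fold or more higher in PB-Tcf1 and 1702 (12.6%) were 2-fold or more lower. Differences of 8-fold or more on the same scale were found for 336 higher and 180 lower genes. CER1 (9350), a secreted antagonist of Nodal, BMP and Wnt, had the largest difference, with 1.35 FPKM in PB and 2213 in PB-Tcf1. Next came CST1 (1469), a cystatin, at 0.51 and 1267 FPKM, and FGF17 (8822), at 0.03 and 740.7 FPKM, the lower value being about 1 read. The mesendoderm transcription factor genes EOMES (8320), LHX1 (3975) and MIXL1 (83881) were also among the 12 largest, with the apelin receptor gene APLNR (187), the hyaluronan synthase gene HAS2 (3037) and the kinase gene ZAP70 (7535). PRSS2 (5645), GYPB (2994) and NPPB (4879) completed the 12 and were listed at the floor of 0.01 FPKM in PB and at 171.8, 166.2 and 164.8 FPKM in PB-Tcf1. PRSS2 and GYPB have close copies in the genome, so their reads may be shared with those copies.

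Among genes lower in PB-Tcf1, ALPPL2 (251), a placental-type alkaline phosphatase with close paralogs, was at 416.2 FPKM in PB and 0.13 in PB-Tcf1. The apelin receptor ligand gene APELA (100506013) was at 164.4 and 0.14 FPKM. The 12 lowest also held LECT1 (11061), ACTN3 (89), CYP2S1 (29785), IDO1 (3620), PRDM14 (63978), CDH1 (999), SOX2 (6657), BST2 (684), CACNG7 (59284) and CRABP1 (1381), with differences from -6.88 for LECT1 to -5.31 for CRABP1. The authors' deposited table, whose calls rest on the plain ratio and a test of the reads of these 2 libraries, marked 3259 genes up and 2787 down. It shared 2206 of the 2209 higher and 1700 of the 1702 lower genes, and 484 up and 546 down calls lay under the filter of 1 FPKM. That test compares the libraries and not the conditions, and 62.7% of the genes in the authors' deposited table had an FDR of 0.001 or less. The number of lower genes was 1117 with a filter of 5 FPKM, chosen after seeing the data. It was 2861 with a ratio of estimated reads and its counting interval. A rule of that kind had been laid out beforehand for read counts, and its use on estimated reads was chosen after seeing the data.

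**Figure D1:**
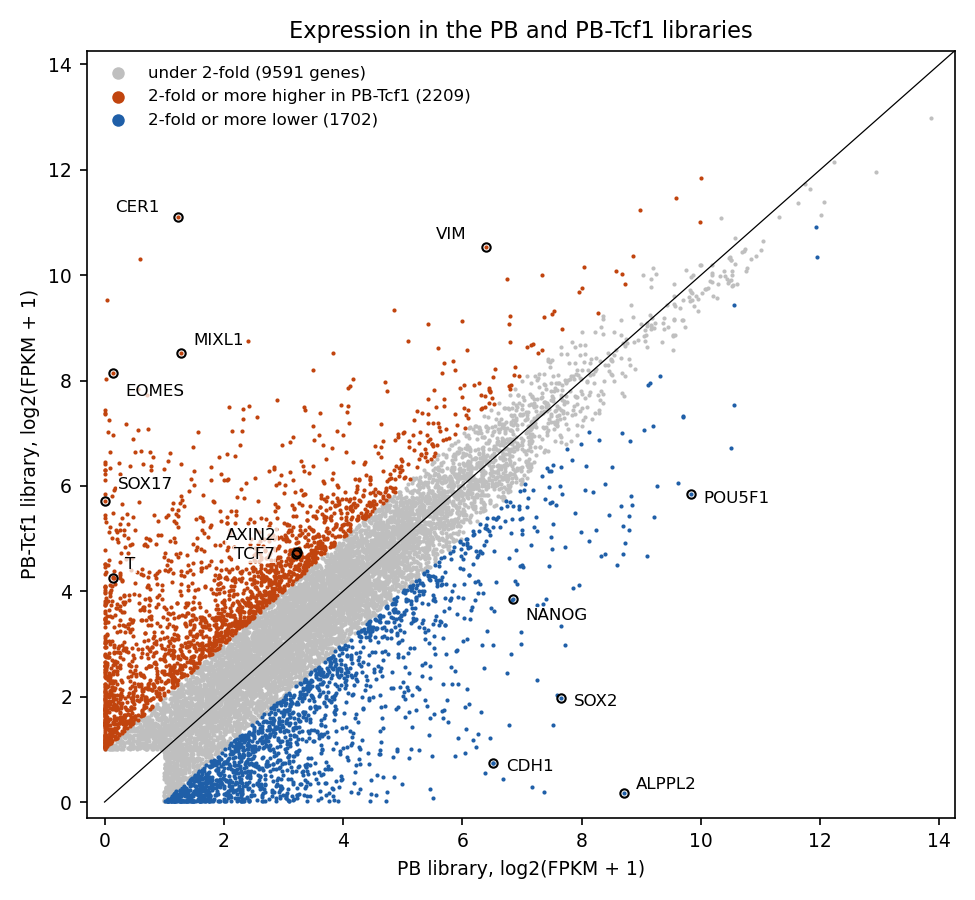
Each point is 1 of 13502 genes that passed the filter, with log2(FPKM + 1) in the PB library on the x axis and in the PB-Tcf1 library on the y axis, the diagonal marking equal values. The 2209 red and 1702 blue points are genes 2-fold or more higher or lower in PB-Tcf1, circled genes are named in the text, and POU5F1, NANOG and SOX2 lie below the diagonal while CER1, EOMES and MIXL1 lie above it.

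Genes of the pluripotent state were lower in PB-Tcf1. POU5F1 (5460), NANOG (79923) and SOX2, the core transcription factor genes of pluripotency, were at 909.7, 113.8 and 201.2 FPKM in PB and at 56.3, 13.5 and 2.95 FPKM in PB-Tcf1. This left 6.19%, 11.8% and 1.47% of the PB level. PRDM14, a regulator of human pluripotency, was at 90.7 and 0.67 FPKM, or 0.739% of the PB level. In the list of core and primed pluripotency genes, 18 of 26 measured members were 2-fold or more lower and 2 were higher. The median difference was -3.01, at percentile 0 of matched random lists, whose central 95% ran from -0.23 to 0.42. The 2 higher members were ZIC2, at 15.5 and 52.7 FPKM, and DUSP6, a feedback phosphatase of FGF/ERK signalling, at 2.03 and 41.5 FPKM.

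The list of naive pluripotency genes had 6 of 13 measured members 2-fold or more lower and 2 higher, with a median of -0.98 at percentile 0.28. ALPPL2 led the lower members, followed by NLRP7 at 4.19 and 0.24 FPKM. The higher members were KLF2, at 0.27 and 12.9 FPKM, and KLF5, at 1.75 and 10.7 FPKM. Without the filter the median was -0.40 at percentile 0.35.

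Target genes of Wnt/β-catenin signalling were higher in PB-Tcf1 although IWR1 was in both media. AXIN2 (8313), a negative feedback gene of the pathway used widely as its readout, was at 8.37 FPKM in PB and 25.7 in PB-Tcf1, a ratio of 3.07 with a counting interval of 2.82 to 3.27. SP5 (389058), a transcription factor gene switched on by the pathway, was at 0.04 and 13.1 FPKM. The secreted inhibitor genes DKK1 and DKK4 were at 143.3 and 78.3 FPKM in PB-Tcf1, against 0.29 FPKM and the floor in PB. Of 23 measured members of the list of target and feedback genes, 14 were 2-fold or more higher and 0 lower, with a median of 1.51 at percentile 100. The remaining 9 differed by less than 2-fold on the log2(FPKM + 1) scale, among them WIF1 (1.14 and 0.09 FPKM) and the receptor ligase genes ZNRF3 (3.45 and 2.35 FPKM) and RNF43 (1.12 and 1.25 FPKM), the last picked after its values were seen.

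Wnt ligand, receptor and secreted inhibitor genes were also higher, 18 of 28 measured members by 2-fold or more and 0 lower, with a median of 1.47 at percentile 100. WLS, the carrier needed for Wnt secretion, was at 0.48 FPKM in PB and 132.2 in PB-Tcf1, and WNT9B was at 0.20 and 18.1 FPKM. The largest differences downward among the measured members were in LGR4, at 46.4 and 26.8 FPKM, and FZD6, at 6.46 and 4.15 FPKM. SFRP2, a secreted Wnt inhibitor gene that stood in the list of core and primed pluripotency genes and not in this list, was lower, at 125.7 and 8.39 FPKM, and was picked after its values were seen. Without the filter the list median was 0.55, and with a pseudocount of 0.1 FPKM, chosen after seeing the data, it was 2.37, both at percentile 100.

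Primitive streak genes showed the largest median of all lists. T (6862), the brachyury gene of the streak and early mesoderm, was at 0.10 FPKM in PB and 18.1 in PB-Tcf1, EOMES at 0.10 and 281.7, MIXL1 at 1.44 and 365.1, and LHX1 at 0.02 and 261.0 FPKM. Of 18 measured members of the streak and mesendoderm list, 17 were 2-fold or more higher, and the median of 4.11 stood at percentile 100. The exception was FOXH1, a partner of SMAD2/3, at 77.3 and 16.5 FPKM.

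Endoderm genes were higher as well, 18 of 21 measured members by 2-fold or more and 0 lower, with a median of 3.33 at percentile 100. GATA6 was at 0.04 FPKM in PB and 128.9 in PB-Tcf1, after CER1 the largest difference in the list. SOX17, GATA4 and FOXA2, endoderm transcription factor genes picked after their values were seen, were listed at the floor in PB and at 51.2, 78.4 and 16.0 FPKM in PB-Tcf1. FOXA3 differed by less than 2-fold, at 11.0 and 5.88 FPKM. With a pseudocount of 0.1 FPKM, chosen after seeing the data, the medians of the streak and endoderm lists were 6.53 and 5.15.

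Mesoderm and cardiovascular progenitor genes had 8 of 12 measured members 2-fold or more higher and 2 lower, with a median of 1.33 at percentile 99.98. HAND1 was at 0.07 and 98.5 FPKM and FOXC1 at 0.05 and 34.0 FPKM, while PDGFRA was at 6.08 and 1.92 FPKM and TCF15 at 1.97 and 0.46 FPKM. Only 12 of 25 genes of that list passed the filter, and over the alternatives the median ran from 0.39 without the filter to 2.90 with a pseudocount of 0.1 FPKM.

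**Figure D2:**
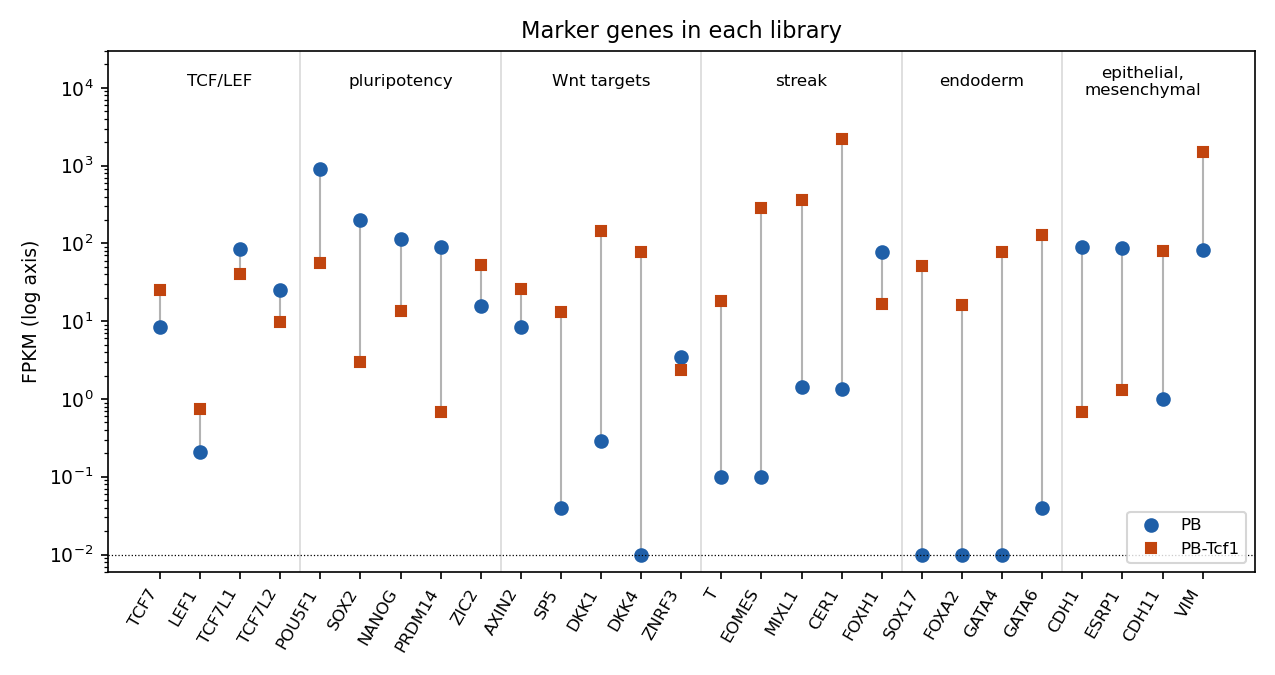
Marker genes on the x axis are shown by their FPKM on a logarithmic y axis, with a circle for the PB library and a square for the PB-Tcf1 library (1 library each), and a dotted line at 0.01, the lowest value listed. POU5F1 drops from 909.7 to 56.3 FPKM while EOMES goes from 0.10 to 281.7 FPKM, and ZNRF3 differs little.

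Ectodermal lists divided. Neuroectoderm genes had 3 of 9 measured members higher, 3 lower, and a median of 0.42 at percentile 87.5, inside the range of random lists. NCAM1 (0.82 and 28.9 FPKM) and CDH2 (14.5 and 185.6 FPKM), adhesion genes also expressed in other lineages, were higher, and POU3F1 (2.70 and 0.15 FPKM) and SOX3 (3.99 and 0.98 FPKM) were lower. The median was 0.02 without the filter and, with a filter of 5 FPKM chosen after seeing the data, 1.45 at percentile 99.9. Neural crest and surface ectoderm genes had 8 of 11 members higher and 1 lower, with a median of 1.71 at percentile 99.98, led by MSX2 (0.43 and 35.0 FPKM) and MSX1 (0.21 and 25.3 FPKM), which are also BMP targets. MSX1 and MSX2 passed the filter through PB-Tcf1 alone, and only 11 of 19 genes of the list passed it. The crest and surface ectoderm genes TFAP2A (0.52 and 0.04 FPKM), PAX3 (0.01 and 0.08), TP63 (0.01 and 0.08), KRT5 (0.01 and 0.12) and KRT14 (0.02 and 0.01) stayed under it. These genes were picked after their values were seen. The list median was 0.47 without the filter and 3.74 with the filter of 5 FPKM, at percentiles 99.85 and 100. The lower member of the list was GRHL2, an epithelial regulator, at 3.94 and 0.03 FPKM. Trophoblast and amnion genes had 5 of 10 members higher, HAND1 and KRT8 (159.8 and 1025 FPKM) most, and 2 lower, KRT7 (3.96 FPKM and the floor) and GABRP (2.57 and 0.04 FPKM). Their median of 0.80 stood at percentile 98.5, but at 77.9 without the filter, 93.9 with 5 estimated reads added and 95.5 with a pseudocount of 0.1 FPKM, and the median ran from 0.05 to 2.30 over the alternatives.

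Signalling readouts differed by pathway. In the Activin/Nodal and SMAD2/3 list 9 of 19 members were higher and 2 lower, with a median of 0.63 at percentile 99.4. CER1 and FGF8 (1.81 and 105.1 FPKM) led upward, and NANOG and FOXH1 downward. BMP target genes had 8 of 12 members higher, again led by MSX1 and MSX2, and a median of 2.14 at percentile 100. Only 12 of 18 genes of the list passed the filter, and without it the median was 0.66, also at percentile 100. Their 1 lower member was ID1, at 242.9 FPKM in PB and 11.6 in PB-Tcf1. FGF/ERK target genes had 9 of 20 members higher and 2 lower, with a median of 0.58 at percentile 98.3. That median was 0.33 without the filter, inside the random range, and 1.15 at percentile 100 with the filter of 5 FPKM. The dual-specificity phosphatase gene DUSP4 (0.40 and 41.3 FPKM) and IER3 (2.45 and 81.4 FPKM) were higher, and ETV4 (63.4 and 23.3 FPKM) and ETV1 (10.9 and 3.55 FPKM) lower. Notch target genes went both ways, 3 of 13 higher and 4 lower, with a median of -0.28 at percentile 8.23 and of -0.11 with the filter of 5 FPKM. DLL3 (2.16 and 26.1 FPKM) and HES1 (2.08 and 22.5 FPKM) were higher, HEY2 (18.2 and 1.07 FPKM) and NRARP (25.1 and 2.56 FPKM) lower.

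Epithelial adhesion genes were lower and mesenchymal genes higher in PB-Tcf1. CDH1, which encodes E-cadherin, was at 90.6 and 0.67 FPKM and the epithelial splicing regulator ESRP1 at 87.1 and 1.32 FPKM. Of 21 members of the epithelial list, 13 were 2-fold or more lower and 1, DSP at 18.1 and 42.3 FPKM, was higher, with a median of -2.16 at percentile 0. In the mesenchymal and matrix list, 15 of 20 members were higher and 1 lower, MMP9 at 2.49 and 0.17 FPKM, with a median of 2.83 at percentile 100. CDH11 was at 0.99 and 79.5 FPKM, COL5A1 at 3.40 and 131.3 FPKM, and VIM, picked after its values were seen, at 83.0 and 1477 FPKM, a ratio of 17.8.

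Some markers of other cell types moved with these groups. Fibroblast and stromal markers had 9 of 11 members higher, led by TAGLN (9.30 and 173.8 FPKM) and COL1A2 (16.4 and 236.2 FPKM), and a median of 2.35 at percentile 100. THY1, a stromal marker also carried by human pluripotent cells, was lower, at 152.0 and 3.95 FPKM. Blood and endothelial markers had 5 members above the filter out of 19, all higher, with a median of 2.19 at percentile 99.8. It was 0.24 without the filter and 5.06 with 5 estimated reads added. VWF, the von Willebrand factor gene of endothelial cells, was at 0.07 and 7.01 FPKM. The endothelial genes PECAM1 (0.14 and 0.01 FPKM), CD34 (0.24 and 0.09 FPKM), CDH5 (0.01 and 0.02 FPKM) and TEK (0.36 and 0.68 FPKM) stayed under the filter. They were picked after their values were seen.

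**Figure D3:**
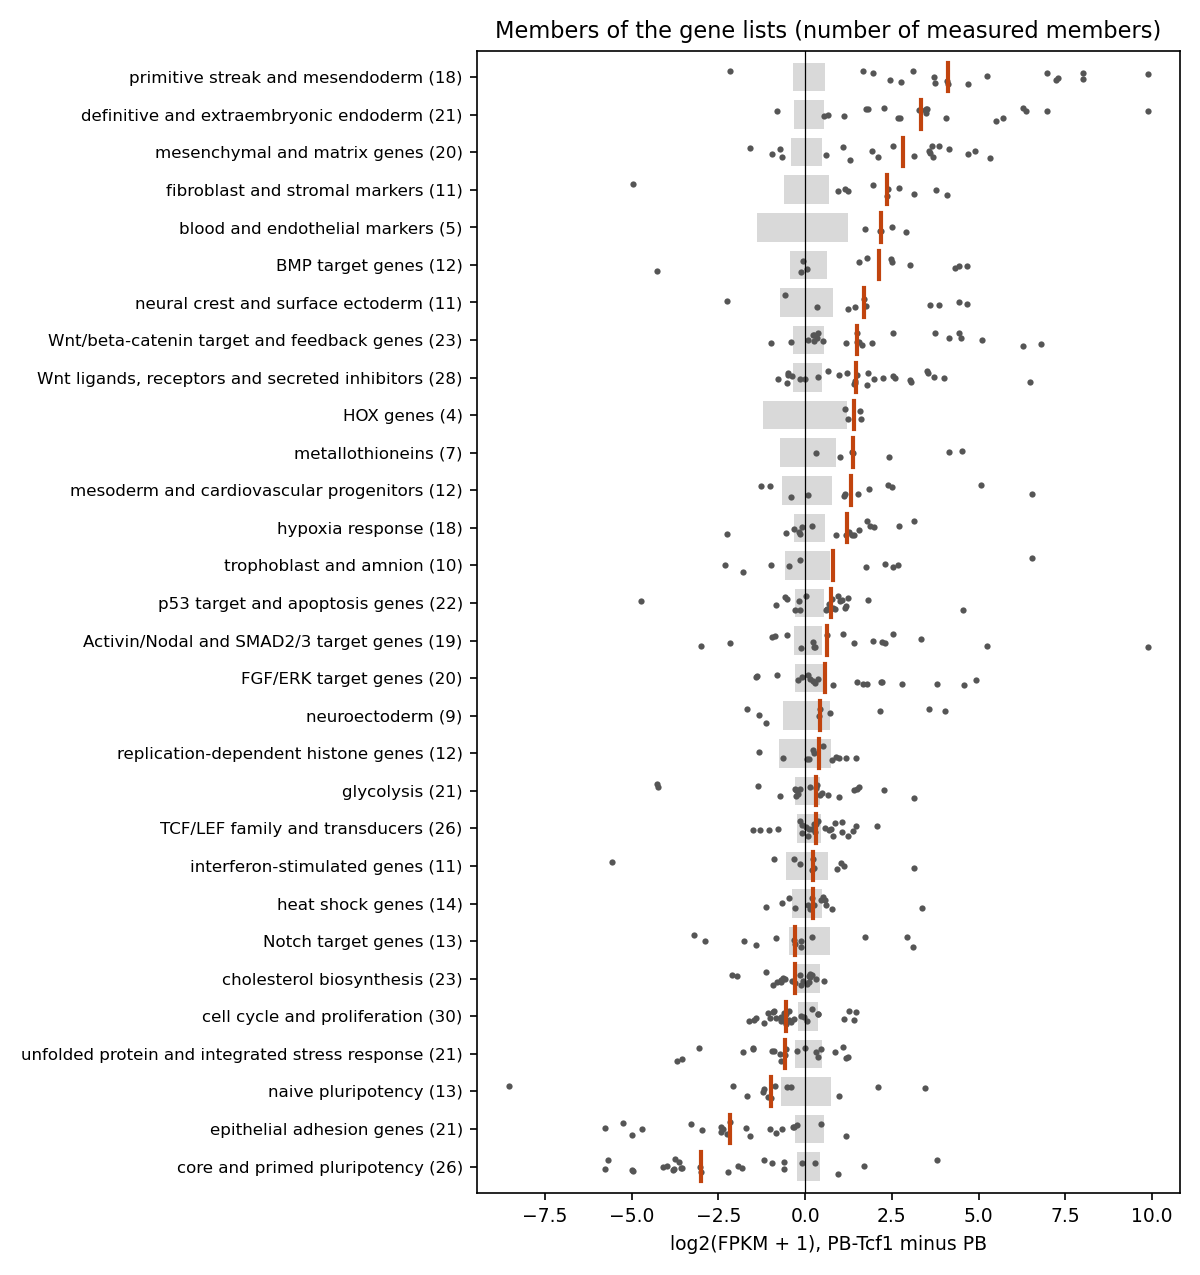
Each point is a measured member of the list named on the y axis, the x axis gives its log2(FPKM + 1) in PB-Tcf1 minus that in PB, the red bar is the list median and the grey band the central 95% of medians of 10000 matched random lists. The median is 4.11 for streak genes at the top and -3.01 for core pluripotency genes at the bottom.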

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

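No list median of 30 changed sign in the alternatives run on lists. Of 127 named genes, 0 of those 2-fold or more apart changed sign under other scalings, a pseudocount of 0.1 FPKM or 5 added reads. That 0 could hardly have differed. A pseudocount added to both libraries cannot reverse a difference, and the scalings moved the log2 ratio by only -0.038 to -0.101. For the same reason TCF7 stayed higher in PB-Tcf1, with ratios of 2.80 to 2.93 under the other scalings. In size, 200 of 635 values of the named genes shifted beyond the gene's counting interval or had no full interval to compare with. Higher genes numbered 1699 to 3259 and stayed within 1.5 times of 2209. Lower genes, 1702 here, numbered 1117 with a filter of 5 FPKM, where fewer genes are tested, 2861 with a ratio of estimated reads and its interval, and 2787 in the authors' deposited table, 546 of them under the filter of 1 FPKM. Those of the 2787 that passed the filter and were not counted here fell short of 2-fold through the pseudocount of 1 FPKM, which the authors' ratio lacks. With a pseudocount of 0.1 FPKM, 2218 genes were lower. The 2861 rests on a ratio without a pseudocount and on a filter of reads in place of FPKM. The part of each was not tested. Median-of-ratios scaling moved the log2 ratio of FPKM by -0.10 for all genes, and the log2(FPKM + 1) of weakly expressed genes by less. It gave 1987 higher and 1870 lower genes. Lists outside the random range numbered 21 to 23, against 23 here. The trophoblast list was lost with no filter, a pseudocount of 0.1 FPKM or 5 added reads, and the FGF/ERK list with no filter. The cholesterol list was lost with unmatched random lists (percentile 3.65), and the neuroectoderm list was gained with a filter of 5 FPKM. Only 29 lists kept enough members for a value with a filter of 100 estimated reads, and 27 with 5 FPKM. The HOX list had no value under either filter and the blood and endothelial list none at 5 FPKM. Both were outside the random range here. List medians moved by over 1.5 times in 12 lists without the filter and in 9 with a pseudocount of 0.1 FPKM. The pseudocount of 0.1 FPKM, the filter of 5 FPKM, trimmed mean scaling, the total without mitochondrial rRNA and the ratio of estimated reads were chosen after seeing the data. Of these, trimmed mean scaling and a ratio with its counting interval had been laid out beforehand for read counts, and only their use here came later. No paired analysis was possible because each group has 1 library. Read numbers are estimates, and values at a few reads in PB limit the size, not the side, of the largest differences.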

Other observations

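All tests of explanations in this part were chosen after the results were seen.

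Hypoxia response genes were higher in PB-Tcf1, 10 of 18 measured members by 2-fold or more against 1 lower, with a median of 1.22 at percentile 100. PDK1 was at 6.57 FPKM in PB and 65.9 in PB-Tcf1 and ADM, adrenomedullin, at 6.45 and 47.7 FPKM, while DDIT4 was lower, at 35.5 and 6.60 FPKM. Glycolysis genes went both ways, 5 of 21 higher and 3 lower, with a median of 0.32 at percentile 92.6. PKM was at 502.6 and 2427 FPKM, whereas ENO2 was at 68.4 and 2.61 FPKM and ALDOC at 52.99 and 1.85 FPKM. In the list of unfolded protein and integrated stress response genes, 6 of 21 members were lower and 3 higher, with a median of -0.58 at percentile 0.08. Its most strongly lower members make serine and asparagine, PHGDH at 335.7 and 25.1 FPKM and ASNS at 167.5 and 13.5 FPKM, while HERPUD1 (8.40 and 21.2 FPKM) and DNAJB9 (4.04 and 10.4 FPKM), genes of the endoplasmic reticulum, were higher. Cholesterol synthesis genes had 3 of 23 lower, with FDFT1 at 450.6 and 114.5 FPKM, and a median of -0.30 at percentile 1.41, or 3.65 among unmatched random lists, inside the random range.

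Cell cycle genes were slightly lower, with 6 of 30 members 2-fold or more lower, 4 higher and a median of -0.54 at percentile 0.01. BUB1 was at 75.3 and 24.1 FPKM and MCM3 at 113.5 and 40.3 FPKM, while CCND2 (19.2 and 55.3 FPKM) and TYMS (29.7 and 80.3 FPKM) were higher. In the p53 target and apoptosis list 6 of 22 were higher, with a median of 0.74 at percentile 99.8. BTG2 was at 3.15 and 95.9 FPKM, and the 1 lower member, PMAIP1, at 210.3 and 6.90 FPKM. Metallothionein genes had 5 of 7 higher and a median of 1.37 at percentile 99.7, with MT2A at 9.15 and 180.1 FPKM and MT1E at 1.21 and 50.04 FPKM, though members of this family resemble each other closely and may share reads, and over the alternatives the median ran from 1.29 to 2.52. HOX genes were weakly expressed. Of the 39 genes of the list, 28 were in the table and 4 passed the filter. These 4, HOXB2, HOXB3, HOXB6 and HOXB7, the last 2 picked after their values were seen, reached 1.24 to 2.67 FPKM in PB-Tcf1, against 0.01 to 0.20 FPKM in PB, with a median of 1.40 at percentile 99.5. They passed the filter through PB-Tcf1 alone, and the median was 0.07 without the filter and 3.63 with a pseudocount of 0.1 FPKM. Interferon-stimulated genes (3 of 11 higher, 1 lower, median 0.24 at percentile 75.6), heat shock genes (1 of 14 higher, 1 lower, 0.22 at percentile 80.4) and replication-dependent histone genes (2 of 12 higher, 1 lower, 0.39 at percentile 83.6) stayed inside the random range. Over the alternatives their medians ran from 0.01 to 0.93, 0.12 to 0.25 and 0.16 to 1.19. Within them BST2 was at 190.4 and 3.07 FPKM, and the co-chaperone gene BAG3 at 11.1 and 124.8 FPKM.

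The mitochondrial ribosomal RNA row RNR2 held 4.10% of estimated reads in PB and 2.21% in PB-Tcf1, and 82 ribosomal protein genes held 6.21% and 4.96%. Of 446 loci without a symbol that passed the filter, 97 were 2-fold or more higher and 89 lower.

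Streak and endoderm genes were higher and pluripotency genes lower in PB-Tcf1. The smallest of the 3 list medians was 3.04 in size under the scaling alternatives. These moved the log2 ratio by only -0.038 to -0.101, so that value could hardly have differed and adds no support. A single factor moves the log2 ratio of every gene the same way. The medians were 4.107 and 3.327 for the streak and endoderm lists and -3.005 for the pluripotency list. Their opposite signs argue against library scaling as the whole cause. For GC content and gene length, the smallest median was 2.88 in size after the median of genes of like GC content and length was taken off. The median difference was 0.008 in the lowest and 0.245 in the highest of 10 GC bins. In the shortest and longest of 5 length bins it was 0.019 and 0.099. Taking off such small values could hardly have brought the list medians near 0, so the 2.88 adds no support. The small bin medians themselves argue against GC content and gene length as the whole cause. Exchanged labels stay open: the TCF7 ratio of 3.005 goes with the labels, but the construct's share of those reads is unknown. A difference between the cultures unrelated to the construct was not tested, and with 1 library per group an effect of Tcf1 expression is a hypothesis.

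POU5F1 kept 6.19% of its PB level, which may come from a fixed share of unchanged PB-like cells in the PB-Tcf1 culture. In that case no other pluripotency gene would keep less. Of 17 other 2-fold lower members of the list, 6 (SOX2, DPPA2, PRDM14, FGF2, THY1 and USP44; DPPA2, FGF2 and USP44 named after their values were seen) had a counting interval wholly below that of POU5F1, down to 0.739% for PRDM14, which argues against such cells as the whole source of its remaining RNA. Among the genes lowest in PB-Tcf1, LECT1 kept 0.154%, APELA 0.0851% and ALPPL2 0.0312%. The upper bounds of their counting intervals were 0.302%, 0.161% and 0.0589%. Of 3370 genes at 20 FPKM or more in PB, 16 kept under 1%. These genes were picked for their low values, but a fixed share of unchanged cells would leave every gene at least about that share. They argue against a share of 1% or more in this culture, as far as counting error goes. A smaller share of unchanged cells, and unequal loss of these RNAs in all cells or in some, stay open.

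Wnt/β-catenin target genes were higher in the presence of IWR1. Counting noise of weakly expressed genes is argued against for 19 of all 23 measured members, whose counting interval of the ratio lay wholly above 1 on estimated reads. For 2 members it lay wholly below 1. At this depth the count had little room to differ. The 14 members 2-fold or more higher differ by at least 1 FPKM, and 1 read in a gene of 2000 bases was worth 0.021 FPKM in PB-Tcf1. In the authors' deposited table, 62.7% of all genes had an FDR of 0.001 or less, in either direction. The 19 of 23 thus add no support beyond the list median. Variation between cultures is not covered by the counting intervals and stays open. Whether the higher levels come from Tcf1 at these genes, from the higher Wnt ligand genes or from incomplete inhibition was not tested, and the activity of IWR1 in these cultures was not measured in these data.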
